A study of Homo sapiens with 12 samples.

How the data were processed

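Libraries of WI-38 fibroblasts were prepared with a kit that sequences the 3' ends of messenger RNA, per the labels' protocols, so that each transcript gives about 1 fragment and values need no correction for length. The submitters' processing notes name STAR 2.5.3a, featureCounts, edgeR and the hg38 genome build; parameters, strand setting and annotation are not given in the sources used here. The deposited table holds 1 signal value per gene and library, which the file's layout and values show to be CPM scaled by the authors with edgeR's TMM factors. The deposited signal values were whole multiples of what 1 read is worth in each library, within a tolerance of 0.01 reads, for 100% of values, which gave back whole reads. The recovered library totals lay between 17790774 and 20650727 reads. TMM factors recomputed from these reads ranged from 0.969 to 1.025 and matched the deposited scaling. Every gene in the table had a plain CPM above 1 in at least 2 libraries, so genes below that level are not analysed here. A gene listed at 0 in a library could be present at up to the worth of 3 reads, 0.142 to 0.170 CPM depending on the library, which covers counting error only.

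Libraries were assigned to 6 groups of 2 from their titles, and each replicate number occurs once, so no pairing was used. The table names genes by symbol, some of them older ones (CYR61 for CCN1, CTGF for CCN2, MB21D1 for CGAS, TMEM173 for STING1). Of 13937 symbols, 12571 (90.2%) were found in GENCODE release 29 on GRCh38, which gave the positions printed; the authors' own annotation may differ. Genes that share sequence with close relatives, such as the CXCL1 to CXCL3 chemokines, the keratin-associated KRTAP2-3 and the IFIT genes, are uncertain as far as read assignment could split them, and reads of overlapping or antisense genes could not be told apart.

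The design had been written for CPM and was kept. Values were tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity-dependent prior), on 13894 genes with at least 1 CPM in at least 2 libraries. All 12 libraries entered a single fit with 6 residual degrees of freedom and 10.1 prior degrees of freedom. The 9 contrasts were YT, cGAS and STING against control, each doubly treated group against its cGAS, STING and YT counterpart, and the interactions of the YAP/TAZ siRNAs with the cGAS and STING siRNAs. P-values were adjusted by Benjamini-Hochberg within each contrast, at a threshold of 0.05.

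The 20 gene lists, fixed before the data were examined along with the contrasts, the alternatives and the rule for named genes, held 409 measured genes of 439. They covered YAP/TAZ targets, Hippo and TEAD genes, cell cycle, nuclear envelope, Arp2/3, contractile genes, extracellular matrix, the senescence-associated secretory phenotype, interferon-stimulated genes, NF-kB targets, the cGAS-STING pathway, p53 targets, senescence genes, cholesterol synthesis, stress response, TGF-beta, hypoxia, mitochondrial and ribosomal transcripts and markers of other cell types. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the 20 lists within a contrast. Lists overlap: AREG, CXCL8 and IL1B are secretory factors, CXCL8 is also an NF-kB target, and GDF15 is in both the p53 and the secretory list.

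Named genes were the targeted genes, the 12 most raised and 12 most lowered genes of YT against control and the 5 of each other contrast among those past the threshold with a mean of at least 5 CPM and no overlap between groups (interactions without the overlap condition), up to 4 members of each list by smallest p, and LMNB1, ACTR2, CDKN1A, IL6, CXCL8, CYR61, CTGF, ANKRD1, IFIT1 and MX1. The text gives a selection of them.

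The alternatives were pseudocounts of 0.25 and 4, no filter or a minimum of 5 CPM, rescaling by the median of ratios, a constant prior, fits of only the groups compared, each library left out in turn, and count tests on the recovered reads. On those reads edgeR 4.0.16 (quasi-likelihood) called 2815 genes higher and 2844 lower in YT against control, and DESeq2 1.42.0 called 2793 and 2698, beside 2865 and 2908 by limma. Where a left-out library leaves a group with a lone sample, that sample is assumed to vary like the other groups.

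The pipeline was tested on simulated counts drawn for the 13894 genes at the real depths. In the YT group alone, 67, 67 and 66 genes with a mean of at least 5 CPM were changed 1.5-fold, 2-fold and 4-fold. For YT against control limma recovered 55.2%, 98.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 13 false among 182 calls. For the cGAS interaction it recovered 23.9%, 79.1% and 100%, with 13 false among 148 calls.

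A search for siRNA seed matches related the log2 changes of 9611 genes with a mean of at least 5 CPM and a 3' UTR of at least 50 bases to each of 15672 heptamers in the UTR, after adjustment for the UTR's GC content and length and the gene's mean CPM, with the strongest association compared with those of 100 permutations of the changes over genes. It was written in Python 3.11.15 with numpy 2.4.6.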

Results

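Transcript levels were measured by 3' end sequencing in WI-38 cells, a line of human embryonic lung fibroblasts, after transfection with small interfering RNAs (siRNAs). The 12 libraries fell into 6 groups of 2. The control group received a control siRNA, and the YT group received siRNAs against YAP1 and WWTR1, which encode the Hippo pathway coactivators YAP and TAZ. The cGAS and STING groups received siRNAs against the cytosolic DNA sensor cGAS or its adaptor STING. The cGAS_YT and STING_YT groups received these together with the YAP and TAZ siRNAs. Each library's title has 2 siRNA positions, and the control siRNA fills both in the control group. In the YT, cGAS and STING groups the control siRNA fills the position that the other siRNAs leave free. The libraries held between 17790774 and 20650727 reads over 13937 genes. Nothing in the labels says that replicate libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All tests below are limma tests on log2(CPM + 1) with Benjamini-Hochberg adjustment, and a change is given as log2 ± SE with 2 libraries per group; on this scale the change of weakly expressed genes is understated. Replicates correlated at 0.987 or more across genes, and the YT libraries differed most from each other, with 249 genes more than 2-fold apart against 77 in the control group.

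The targeted transcripts were low in the libraries whose labels name them. YAP1 (chromosome 11, 102110461 to 102233423, GRCh38) was at 109 ± 6.38 CPM (SD, n = 2) in control cells and 14.6 ± 2.30 CPM in YT cells, which left 13.4%. WWTR1 (chromosome 3, 149517235 to 149736714) was at 139 ± 8.07 and 19.8 ± 4.31 CPM, which left 14.2%. Relative to cells with cGAS siRNAs alone, 24.8% of YAP1 and 19.2% of WWTR1 were left in cGAS_YT cells. Relative to cells with STING siRNAs alone, 16.2% and 12.02% were left in STING_YT cells. Relative to control, YAP1 was at 21.15% in cGAS_YT and 13.09% in STING_YT cells, and WWTR1 at 13.21% and 8.7%. WWTR1 was at 93.51 and 97.69 CPM in the cGAS libraries and at 101.7 and 99.19 CPM in the STING libraries, below control. The cGAS gene, listed under its older symbol MB21D1, was at 7.87 ± 2.45 CPM in control cells and 1.85 ± 0.121 CPM after cGAS siRNAs, or 23.5% of control. The STING gene, listed as TMEM173 (chromosome 5, 139475534 to 139482935), was at 24.1 ± 0.608 CPM in control cells and 1.78 ± 0.0110 CPM after STING siRNAs, or 7.39% of control.

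**Figure D1:**
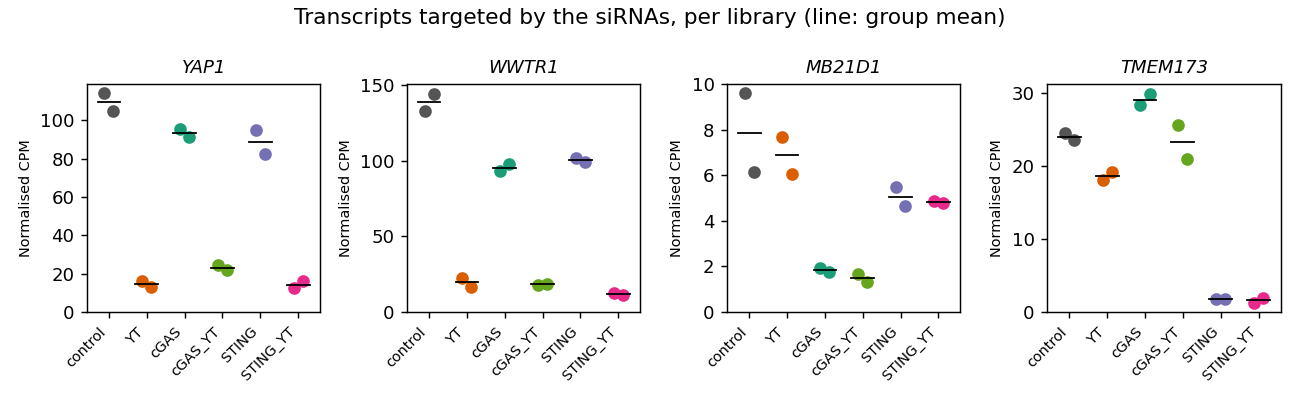
Normalised CPM of the 4 transcripts targeted by the siRNAs (linear axes from 0), with 1 point per library, 2 libraries per group, and a line at the group mean. YAP1 was at 14.6 CPM in YT, 23.1 CPM in cGAS_YT and 14.3 CPM in STING_YT cells, against 109 CPM in control cells.

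The comparison of YT with control asked what the YAP and TAZ siRNAs changed in fibroblasts. CXCL1, a neutrophil chemokine, had the largest rise of the named genes: it went from 1.33 to 394 CPM (7.56 ± 0.40, adjusted p = 4.61e-10), and CXCL8, another neutrophil chemokine, rose by 6.98 ± 0.40. Libraries differed in both: CXCL8 stood at 493 and 145.7 CPM in YT replicates 3 and 4 (a rise of 6.10 without replicate 3 and 7.85 without replicate 4), and CXCL1 at 2.49 and 0.170 CPM in control replicates 1 and 2 (8.35 without control replicate 1 and 6.77 without control replicate 2). PTGS2, the inducible cyclooxygenase, rose by 7.18 ± 0.23, the cytokine genes IL24 and IL1B by 6.25 ± 0.25 and 5.47 ± 0.28, and C11orf96 by 5.79 ± 0.25. Of 24 NF-kB targets, 23 rose and none fell (also 23 adjusted over the list alone), with a median of 2.08, among them the NF-kB inhibitor NFKBIA (2.20 ± 0.09) and TNFAIP3 (3.48 ± 0.18). Of 29 factors of the senescence-associated secretory phenotype 21 rose and 2 fell (22 and 3 adjusted over the list alone), with AREG at 4.79 ± 0.17 and IL1A at 5.39 ± 0.24. IL6 was not called (-0.09 ± 0.53): it stood at 11.2 and 0.926 CPM in YT replicates 3 and 4, against 4.17 ± 0.270 CPM in control cells, and it was lower than control without replicate 3 (-1.42, adjusted p = 0.000538) and higher without replicate 4 (1.25, adjusted p = 0.00176).

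Most of the cell cycle, YAP/TAZ target and contractile genes fell in the same comparison. The oxytocin receptor gene OXTR fell by 4.77 ± 0.11 and the YAP/TAZ target CYR61 by 3.52 ± 0.13, from 478 to 41.7 CPM. LMNB1, which encodes lamin B1, went from 30.5 ± 1.30 to 2.40 ± 0.103 CPM (-3.21 ± 0.18, adjusted p = 1.1e-09), and ACTR2, a subunit of the actin-nucleating Arp2/3 complex, from 536 ± 6.85 to 144 ± 19.6 CPM (-1.90 ± 0.09). All 30 cell cycle genes fell (30 adjusted over the list alone; median -2.22), with TOP2A, a topoisomerase of dividing cells, at -2.80 ± 0.12. Of 22 YAP/TAZ target genes 15 fell and 1 rose (16 and 1 adjusted over the list alone), including CTGF (-2.69 ± 0.15) and AMOTL2 (-1.55 ± 0.09). Of 23 contractile and focal adhesion genes 20 fell (22 adjusted over the list alone), such as ACTG2 (-1.39 ± 0.09), TPM1 (-1.16 ± 0.08) and CNN1 (-1.26 ± 0.09). In the Arp2/3 complex 6 of 9 members fell (6 adjusted over the list alone), and among cytosolic ribosomal protein genes 19 of 27 fell (21 adjusted over the list alone; median -0.34). The cell cycle inhibitor gene CDKN1A rose by 0.42 ± 0.10.

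In all, 2865 genes rose and 2908 fell of 13894 tested in YT against control, of which 605 and 700 changed at least 2-fold. Camera gave adjusted p = 3.31e-19 for the NF-kB targets and 9.71e-24 for the cell cycle genes, and these 2 lists held, each at adjusted p = 0.0328 with an estimated correlation. The calls of the other lists were lost with an estimated correlation. The YAP/TAZ targets, the contractile genes and the Arp2/3 complex each had adjusted p = 0.0956, the secretory list 0.166 and the ribosomal genes 0.40. By fry these lists passed (adjusted p = 1.61e-05, 2.39e-05, 1.86e-05, 5.24e-05 and 0.0106 in that order). Fry also passed the p53 targets (adjusted p = 2.39e-05) but not the interferon-stimulated genes (0.173). The interferon-stimulated genes, of which 22 of 40 rose (23 adjusted over the list alone; median 0.70) with MX1 at 1.65 ± 0.41, had adjusted p = 0.52 with an estimated correlation. Among p53 targets 11 of 25 rose and 2 fell (12 and 3 adjusted over the list alone; adjusted p = 0.0956 with an estimated correlation), with GDF15 at 2.69 ± 0.10 and ZMAT3 at -1.19 ± 0.08. The remaining 11 lists did not pass camera: 7 genes of the cGAS-STING pathway rose and 1 fell of 14, 6 and 8 of 20 in the Hippo and TEAD list, 4 and 7 of 16 in the nuclear envelope list, and 6 and 7 of 30 in the extracellular matrix list. Of 15 senescence genes 7 rose and 4 fell, of 22 cholesterol genes 7 and 1, of 21 stress response genes 6 and 3, of 20 TGF-beta genes 9 and 5, and of 19 hypoxia genes 3 and 8. None of 13 mitochondrially encoded transcripts passed, and of the 3 markers of other cell types above the filter KRT15, an epithelial keratin, fell (-0.93 ± 0.30). Adjusted over the list alone, the counts of these 11 lists were the same except for 10 lower Hippo and TEAD genes, 10 higher TGF-beta genes and 1 higher marker. Of these 11 lists, fry passed the nuclear envelope (adjusted p = 2.39e-05), Hippo and TEAD (0.0015), hypoxia (0.0015) and cGAS-STING lists (0.002). It also passed the cholesterol (0.00397) and stress response lists (0.00399), but not the others.

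**Figure D2:**
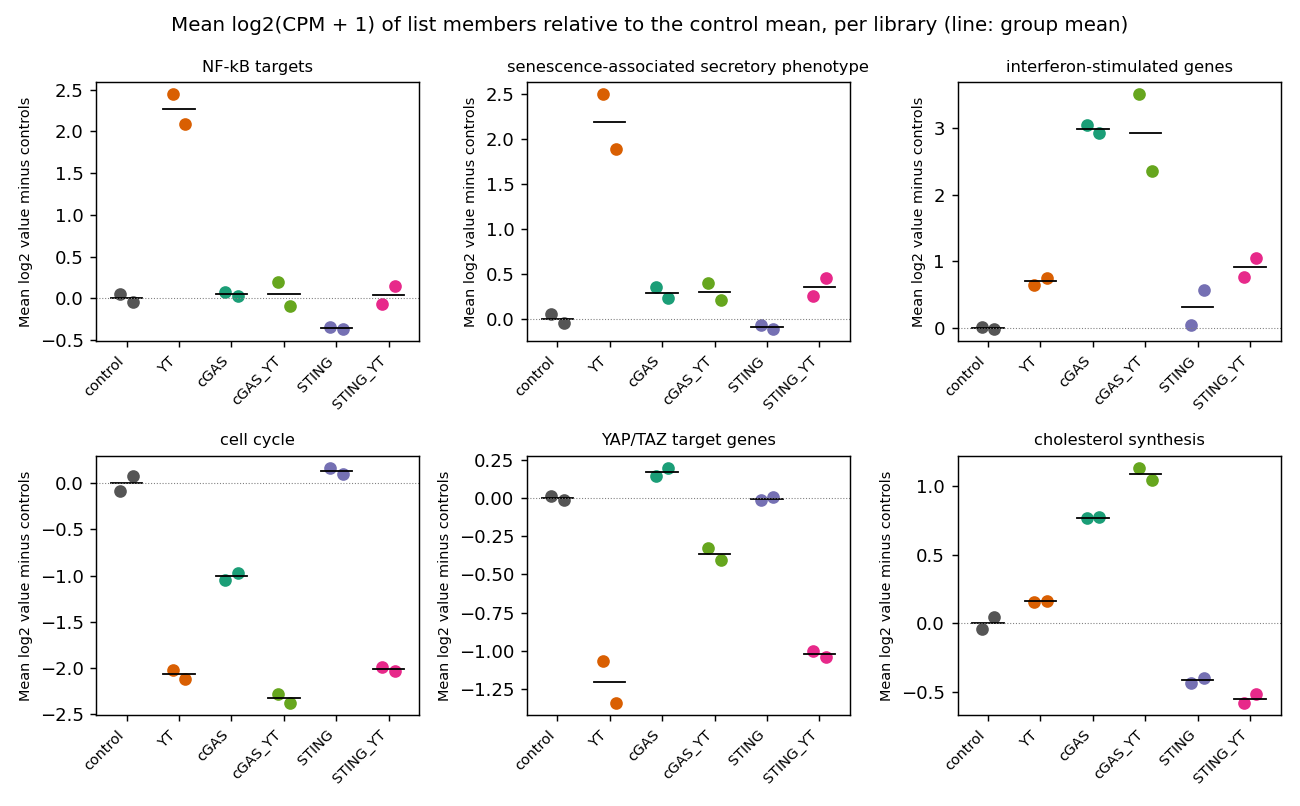
Mean log2(CPM + 1) of the members of 6 gene lists minus the mean of the control libraries (linear axes), with 1 point per library, 2 libraries per group, and a line at the group mean. The NF-kB targets stood at 2.44 and 2.09 in the YT libraries and at 0.19 or less in every other library outside the control group; interferon-stimulated genes stood at 2.35 or more in the 4 libraries with cGAS siRNAs.

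The cGAS siRNAs alone were compared with control to show the background against which YAP and TAZ were depleted. All 40 interferon-stimulated genes rose (40 adjusted over the list alone; median 2.85, adjusted p = 0.188 with an estimated correlation), with the antiviral genes OAS2 at 5.71 ± 0.39, IFI44L at 5.69 ± 0.27 and MX1 at 5.46 ± 0.41, the last from 11.4 to 542 CPM. Of 22 cholesterol synthesis genes 19 rose (20 adjusted over the list alone), led by HMGCS1, which makes the precursor of mevalonate (1.91 ± 0.09). Of 30 cell cycle genes 27 fell (29 adjusted over the list alone; median -1.04), and LMNB1 fell by 1.60 ± 0.18. The chromatin protein gene HMGA2 fell by 3.06 ± 0.12, from 742 to 88.3 CPM, the myosin light chain gene MYL6 by 2.67 ± 0.10, the hyaluronan-degrading CEMIP by 2.75 ± 0.17 and the plasminogen activator gene PLAT by 2.64 ± 0.10. Ribosomal protein genes fell (24 of 27; 27 adjusted over the list alone; median -0.44). In all, 1543 genes rose and 1985 fell.

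Cell cycle and cholesterol lists held in this comparison (adjusted p = 0.0434 and 0.0268 with an estimated correlation). The interferon list passed camera at the preset correlation (adjusted p = 6.37e-42) but not with an estimated one. The ribosomal list had adjusted p = 0.373 with an estimated correlation. By fry the interferon and ribosomal lists passed (adjusted p = 0.000853 and 0.00677). The count of 3528 genes was 2050 without cGAS replicate 7, 2255 without cGAS replicate 8 and 2239 without control replicate 2.

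The STING siRNAs alone changed fewer genes, 853 higher and 1231 lower, and this difference in number was not tested. ADAM19, which encodes a cell surface protease, fell by 2.57 ± 0.07, CMTM6 by 2.23 ± 0.10 and DIO2, a deiodinase of thyroid hormone, by 2.12 ± 0.11. The interferon-stimulated genes IFI6 and IFI27 rose by 2.22 ± 0.21 and 1.99 ± 0.26, among 4 of 40 that rose (3 adjusted over the list alone; median 0.19, adjusted p = 0.756 with an estimated correlation); MX1 was not called (0.45 ± 0.41). Cholesterol synthesis genes fell (11 of 22; 14 adjusted over the list alone), such as MVD (-1.23 ± 0.16), and so did 12 of 20 TGF-beta response genes (15 adjusted over the list alone), such as COL7A1 (-1.43 ± 0.13) and PMEPA1 (-0.97 ± 0.12), with 1 that rose. Of 24 NF-kB targets 9 fell (9 adjusted over the list alone), BIRC3 by 1.09 ± 0.15, as did 11 of 23 contractile genes (11 adjusted over the list alone), ACTA2, the smooth muscle actin, by 1.16 ± 0.10. No list passed here once the correlation was estimated: the cholesterol and TGF-beta lists each had adjusted p = 0.0734 with an estimated correlation, the NF-kB targets 0.287 and the contractile genes 0.30. The count of 2084 genes was 1105 without control replicate 1, 1317 without control replicate 2, 941 without STING replicate 13 and 879 without STING replicate 14.

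The effects of the cGAS and STING siRNAs share the control libraries. Across genes, which are not independent replicates, their log2 changes correlated at r = 0.234, below the 0.502 of simulated unchanged groups against shared controls, and their covariance was 0.0402 against 0.0183 simulated. Genes higher in both numbered 255 (94.7 for independent lists), genes lower in both 372 (176) and genes of opposite direction 252. Part of the excess over independent lists may come from the shared controls. The simulated groups held no changed genes, so their overlap of 0 was set in advance and cannot measure that part.

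Short sequences in 3' UTRs went with the genes that fell. Among 9611 genes, those with the heptamer GCATTCA, which also occurs in the cGAS transcript (as do 18.8% of all heptamers tested), were lower after cGAS siRNAs (z = -14.12), and those with GTCATAT, which occurs in the STING transcript (as do 10.4%), were lower after STING siRNAs (z = -9.79). Of the genes named above, HMGA2 carries the first, whereas MYL6, CEMIP, PLAT and LMNB1 do not. LMNB1 does have 1 site of the weaker heptamers associated with lower values after cGAS siRNAs. ADAM19, CMTM6 and DIO2 carry the second, and sites in MVD, COL7A1, PMEPA1, BIRC3 and ACTA2 were not listed gene by gene. With YAP and TAZ siRNAs alone the strongest was GGAACTT (z = -7.86), which occurs in a transcript that they target, as do 45.8% of heptamers. The 5th percentile of the strongest association in 100 permutations was -4.36, -4.65 and -4.47 for the 3 comparisons with control.

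**Figure D3:**
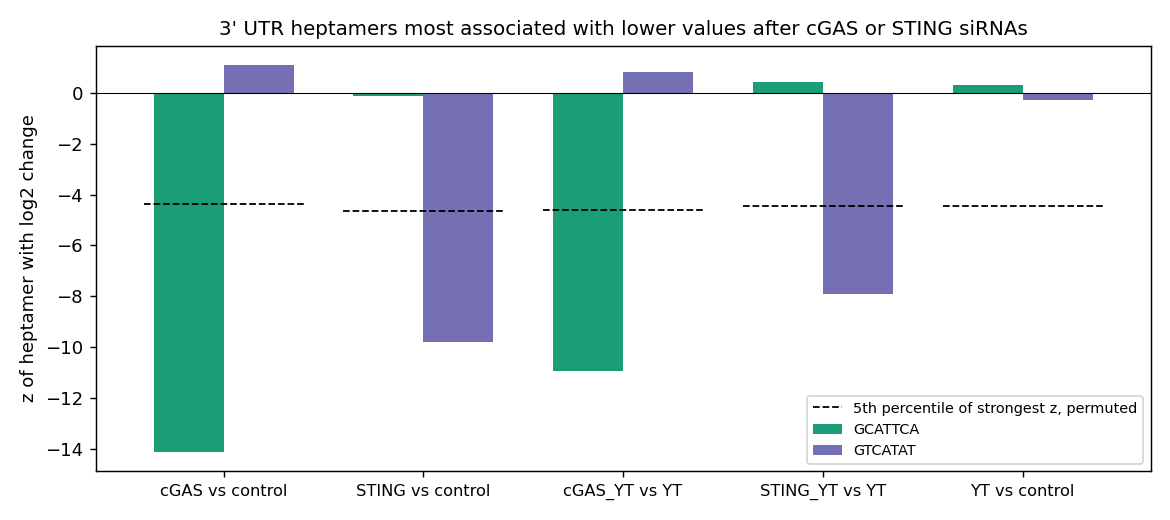
Association (z, linear axis) of 2 heptamers in 3' UTRs with the log2 changes of 9611 genes in 5 comparisons, with dashed lines at the 5th percentile of the strongest association in permuted data. GCATTCA stands at -14.12 and -10.95 in the comparisons that add cGAS siRNAs, and GTCATAT at -9.79 and -7.93 in those that add STING siRNAs.

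Whether YAP and TAZ act alike without cGAS was asked by comparing cGAS_YT with cGAS. Cell cycle genes fell (23 of 30, with 1 that rose; 24 and 1 adjusted over the list alone; median -1.44), with TOP2A at -2.49 ± 0.12 and CDK1, the mitotic kinase, at -2.62 ± 0.23. Of 22 YAP/TAZ targets 15 fell and 3 rose (15 and 3 adjusted over the list alone), with CTGF at -1.71 ± 0.15, and ACTR2 fell by 1.89 ± 0.09. Among p53 targets 19 of 25 rose and 2 fell (20 and 2 adjusted over the list alone), with the mitochondrial regulator SPATA18 at 1.27 ± 0.13. Of 24 NF-kB targets 7 rose and 1 fell (7 and 2 adjusted over the list alone; median -0.01), and CXCL8 was not called (-0.66 ± 0.40). In all, 2087 genes rose and 1761 fell. The cell cycle and p53 lists held (adjusted p = 0.0314 and 0.0258 with an estimated correlation), and the YAP/TAZ targets had adjusted p = 0.195 with an estimated correlation. The 2 cGAS_YT libraries differed in interferon-stimulated genes, MX1 standing at 780 CPM in replicate 9 and 246 CPM in replicate 10, and the list, which did not pass with both libraries, was lower without replicate 9 (camera adjusted p = 2.92e-08) and higher without replicate 10 (4.6e-06). The count of 3848 genes was 2258 without cGAS_YT replicate 10, 2494 without cGAS replicate 7 and 2343 without cGAS replicate 8.

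The same question for STING was asked by comparing STING_YT with STING. All 30 cell cycle genes fell (30 adjusted over the list alone; median -2.51), with TOP2A at -3.32 ± 0.12, and LMNB1 fell by 3.01 ± 0.18 and ACTR2 by 2.07 ± 0.09. Of 22 YAP/TAZ targets 18 fell and 2 rose (18 and 2 adjusted over the list alone), with CTGF at -2.75 ± 0.15 and IGFBP3 at -2.60 ± 0.15. PTGS2 rose by 4.13 ± 0.23, from 1.76 to 48.0 CPM, and AREG by 3.18 ± 0.17. Of 24 NF-kB targets 10 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.44), with VCAM1 at 1.12 ± 0.12, and CXCL8 was not called (0.48 ± 0.40). Of 40 interferon-stimulated genes 16 rose (16 adjusted over the list alone; adjusted p = 0.597 with an estimated correlation), and of 25 p53 targets 18 rose and 2 fell (18 and 2 adjusted over the list alone). In all, 2660 genes rose and 2745 fell. The cell cycle and p53 lists held, each at adjusted p = 0.0292 with an estimated correlation, whereas the YAP/TAZ targets had adjusted p = 0.12 and the NF-kB targets adjusted p = 0.443 with an estimated correlation.

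**Figure D4:**
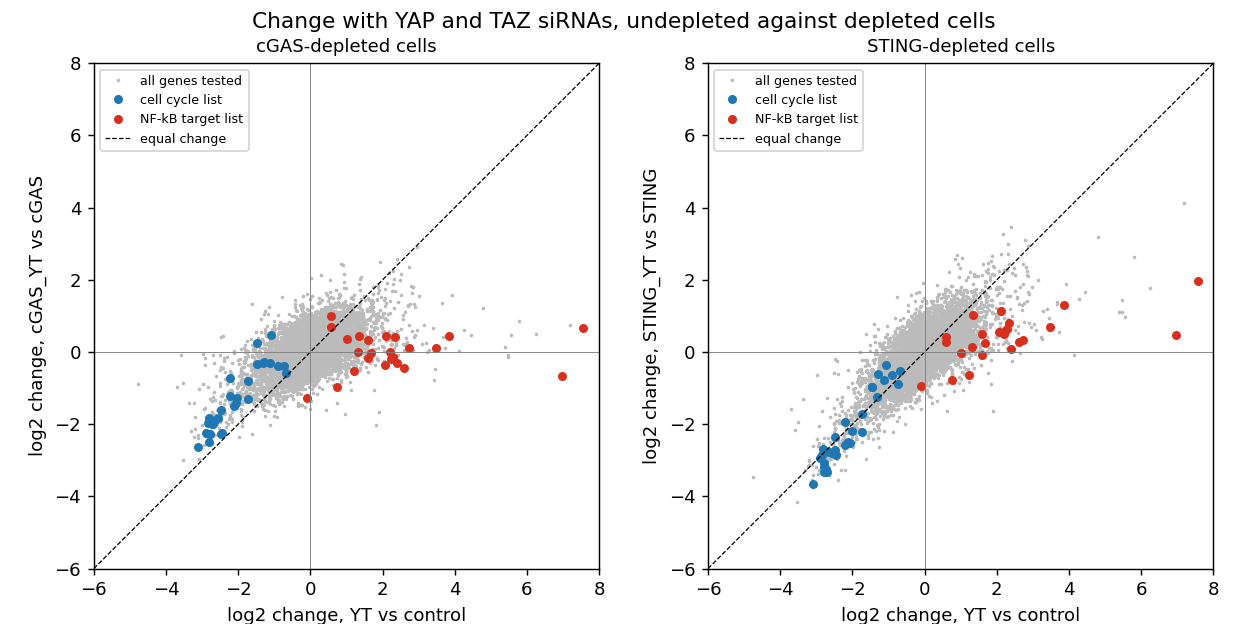
Log2 change of each tested gene with YAP and TAZ siRNAs in cells without other depletion (x axis) against the change in cGAS-depleted (left) or STING-depleted cells (right), with 2 libraries per group and a dashed line of equal change. The NF-kB targets, with a median of 2.08 on the x axis, have medians of -0.01 and 0.44 on the y axes, and the cell cycle genes, with a median of -2.22, have medians of -1.44 and -2.51.

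The difference between the YAP/TAZ effect with and without cGAS was tested as an interaction. It was negative for 21 of 24 NF-kB targets and positive for none (21 adjusted over the list alone; median -1.84, camera adjusted p = 6.78e-30, adjusted p = 0.0201 with an estimated correlation). CXCL8 had an interaction of -7.63 ± 0.56, CXCL1 -6.88 ± 0.56, PTGS2 -6.43 ± 0.33 and IL1B -5.60 ± 0.40. The secretory list had 19 negative and 2 positive members of 29 (20 and 3 adjusted over the list alone; adjusted p = 0.0816 with an estimated correlation). Positive interactions, where a gene that fell in YT cells fell less in cGAS-depleted cells or rose, included OXTR (3.89 ± 0.16), the imprinted gene MEST (3.51 ± 0.26), CYR61 (2.66 ± 0.19) and LMNB1 (1.79 ± 0.26). They covered 13 of 22 YAP/TAZ targets, with 2 negative (15 and 3 adjusted over the list alone), 16 of 23 contractile genes (20 adjusted over the list alone) and 14 of 30 cell cycle genes (21 adjusted over the list alone). These 3 lists had adjusted p = 0.11, 0.0803 and 0.0803 with an estimated correlation. The cGAS siRNAs alone had already lowered the cell cycle list (median -1.04) and LMNB1 (30.5 to 9.44 CPM), and in cGAS_YT cells LMNB1 stood at 2.92 CPM against 2.40 in YT cells. ACTR2 showed no detectable interaction (0.01 ± 0.12).

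In all, 1042 genes had a positive and 824 a negative interaction with cGAS depletion. Between YT and cGAS-depleted cells, medians of the YAP/TAZ effect were smaller in the background where genes had not been chosen. Genes called higher in YT had medians of 0.64 in YT and 0.30 in cGAS-depleted cells. Genes called higher in cGAS_YT against cGAS had 0.44 and 0.61. Among genes called in STING_YT against STING, a choice that uses neither, the medians were 0.48 and 0.40 for higher and -0.48 and -0.35 for lower genes; these differences were not tested. The count of 1866 genes was 3270 without YT replicate 3, 1111 without cGAS replicate 7 and 1183 without cGAS replicate 8. YAP1 was at 23.1 ± 2.06 CPM in cGAS_YT against 14.6 ± 2.30 CPM in YT cells (0.63 ± 0.13, adjusted p = 0.00109), whereas WWTR1 was at 18.3 ± 0.623 against 19.8 ± 4.31 CPM and was not called (-0.09 ± 0.12).

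With STING, the interaction was negative for 20 of 24 NF-kB targets and positive for none (21 adjusted over the list alone; median -1.58, camera adjusted p = 3.65e-30, adjusted p = 0.0197 with an estimated correlation). CXCL8 had an interaction of -6.50 ± 0.56, CXCL1 -5.59 ± 0.56, CXCL5 -4.57 ± 0.37 and IL1B -4.36 ± 0.40. The secretory list had 18 negative members of 29 and none positive (20 negative and 3 positive adjusted over the list alone; adjusted p = 0.161 with an estimated correlation). Positive interactions were found for the Cdc42 effector CDC42EP3 (2.35 ± 0.13), LBH (2.18 ± 0.12), CYR61 (1.57 ± 0.19) and ACTG2 (1.18 ± 0.12), and for 9 of 23 contractile genes (14 adjusted over the list alone; adjusted p = 0.161 with an estimated correlation). Cell cycle genes had 1 positive interaction of 30 (none adjusted over the list alone; the list did not pass camera), and LMNB1 showed no detectable interaction (0.20 ± 0.26). In all, 465 genes had a positive and 630 a negative interaction, and without YT replicate 3 the balance turned, with 1329 positive and 1226 negative. The count of 1095 genes was 2555 without YT replicate 3, 550 and 674 without STING_YT replicates 15 and 16, 583 and 643 without STING replicates 13 and 14, and 703 with a constant prior.

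The interactions share the YT and control libraries. Genes with a negative interaction in both numbered 373 (37.4 for independent lists), genes with a positive one in both 306 (34.9) and genes of opposite sign 7. Part of the excess over independent lists may come from the shared libraries. The simulated groups held no changed genes, so their overlap of 0 was set in advance and cannot measure that part. Across genes the interactions correlated at r = 0.694, against 0.503 for simulated unchanged groups that share the same libraries, with a covariance of 0.177 against 0.0366 simulated, a difference of 0.140. The YAP/TAZ effect across genes correlated at r = 0.575 between YT and cGAS-depleted cells, 0.742 between YT and STING-depleted cells and 0.747 between the 2 depleted backgrounds. Genes higher with YAP and TAZ siRNAs in all 3 backgrounds numbered 995, and genes lower in all 3 numbered 1096.

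Direct comparison of the doubly treated groups with YT gave levels in YAP/TAZ-depleted cells. In cGAS_YT against YT, 20 of 24 NF-kB targets were lower and none higher (21 adjusted over the list alone; adjusted p = 0.0347 with an estimated correlation), CXCL1 by -6.28 ± 0.40 and C11orf96 by -6.10 ± 0.25. Interferon-stimulated genes were higher (36 of 40, with 1 lower; 36 and 1 adjusted over the list alone; adjusted p = 0.366 with an estimated correlation), as was IGF1, a growth factor gene (4.38 ± 0.22). Cholesterol synthesis genes were higher (20 of 22, with 1 lower; 20 and 2 adjusted over the list alone; adjusted p = 0.0347 with an estimated correlation), whereas 16 of 30 cell cycle genes were lower and 3 higher (19 and 4 adjusted over the list alone; adjusted p = 0.505 with an estimated correlation). In all, 2848 genes were higher and 2808 lower. In STING_YT against YT, 23 of 24 NF-kB targets were lower (23 adjusted over the list alone; adjusted p = 0.038 with an estimated correlation), CXCL8 by -6.55 ± 0.40, and 18 of 22 cholesterol synthesis genes were lower (19 adjusted over the list alone, with 1 higher; adjusted p = 0.0435 with an estimated correlation), INSIG1 by -1.41 ± 0.11. The tight junction gene CLDN11 was higher by 3.03 ± 0.09, and 2229 genes were higher and 2502 lower in all. The last count, 4731 in total, was 3015 without STING_YT replicate 15.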

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

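The difference of the YAP/TAZ effect between depleted and undepleted cells was tested as an interaction for every gene and list, and each gene named in the next 2 paragraphs passed it, as each list there passed camera at the preset correlation. The tests of the interferon pattern, of knockdown depth, of other seeds and of the need for cGAS and STING were chosen after the results were seen; those of left-out YT libraries and of the heptamers found were set before theirs were, the latter worded for all seeds and narrowed later. The bar for knockdown depth had been 1 bootstrap SE, which both arms pass, and was raised to 2 after the margins were seen, which leaves the cGAS arm open.

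With cGAS siRNAs 1866 genes differed. The most negative values were those of CXCL8 (-7.63), CXCL1 (-6.88), PTGS2 (-6.43), IL24 (-5.75) and IL1B (-5.60), and the most positive those of OXTR (3.89), MEST (3.51), SHISA3 (2.96), CDC42EP3 (2.92) and KCNJ2 (2.90). LMNB1 (1.79), CYR61 (2.66), CTGF (0.98), ANKRD1 (2.05) and MX1 (-1.95) also differed; without cGAS_YT replicate 10 MX1 was not called (adjusted p = 0.17), and the interferon list did not pass camera (adjusted p = 0.137). Median interactions of the lists past camera were -1.84 for NF-kB targets, -1.50 for the secretory list, -0.70 for interferon-stimulated genes and -0.19 for the stress response list. They were 0.64 for YAP/TAZ targets, 0.74 for cell cycle, 0.34 for the nuclear envelope, 0.22 for Arp2/3, 0.62 for contractile genes, 0.23 for extracellular matrix, 0.30 for p53 targets and 0.14 for ribosomal genes. With an estimated correlation the NF-kB call alone held, and the other adjusted p-values lay between 0.0803 and 0.642.

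With STING siRNAs 1095 genes differed. The most negative values were those of CXCL8 (-6.50), CXCL1 (-5.59), CXCL5 (-4.57), IL24 (-4.49) and IL1B (-4.36), and the most positive those of CDC42EP3 (2.35), RASL11B (2.29), KCNJ2 (2.28), LBH (2.18) and SHISA3 (2.13), with CYR61 at 1.57. Median interactions of the lists past camera were -1.58 for NF-kB targets, -1.37 for the secretory list, -0.35 for cholesterol synthesis, 0.40 for contractile genes, 0.18 for extracellular matrix and 0.13 for ribosomal genes. Here too the NF-kB call alone held with an estimated correlation, the others lying between 0.161 and 0.814.

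With either YT library left out, at least 22 of the 23 raised NF-kB targets still passed in YT against control. That count covers the rise alone, so it cannot decide whether the smaller response in depleted cells rests on a single YT library. The list mean over control was 2.4 and 2.1 in YT replicates 3 and 4, against 0.19 or less in every library of depleted cells. The smaller NF-kB response did not rest on direct matches of the heptamers found in these data. At least 85% of the targets without one had a negative interaction. The siRNA sequences are not given, but direct matches of other seeds would lower the list with or without YAP and TAZ siRNAs. Its medians were -0.10 (cGAS) and -0.31 (STING) against control and -2.06 and -1.86 against YT. They were similar over the 18 members with at least 5 CPM in control cells. Against control, 5 targets rose and 6 fell with cGAS siRNAs, and 0 rose and 9 fell with STING siRNAs. The larger fall against YT is thus not what direct matches alone predict, but the medians cannot exclude matches in single members. The values speak against a weaker knockdown in the STING arm. YAP1 stood at 14.3 CPM against 14.6 in YT cells and WWTR1 at 12.1 against 19.8. The YAP/TAZ targets kept 67.4 percentage points more of their median change than the NF-kB targets (bootstrap SE 33.1). The SE of this margin comes from resampling list members as if independent, and leaves out the spread between libraries. In the cGAS arm that margin was 47.6 points (SE 30.9), under the bar of 2 SEs, the YAP/TAZ targets kept 47.3% of their change, and YAP1 was higher than in YT cells (23.1 CPM) but WWTR1 was not (18.3 against 19.8 CPM), so a shallower knockdown of YAP1 cannot be told apart there. A need for cGAS and STING goes with at least 20 of 24 targets having a negative interaction in each arm. With 1 siRNA pool per gene, however, an off-target effect stays open, indirect or through direct matches in single members.

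The cGAS siRNAs raised interferon-stimulated genes by a median of 2.85. Loss of signalling through cGAS and STING would not predict this pattern, because the STING siRNAs left 7.39% of TMEM173 and moved the same list by a median of 0.194, under 50% of the cGAS value, although the STING libraries differed (list means of 0.05 in replicate 13 and 0.58 in replicate 14, against 3.04 and 2.93 in the cGAS libraries). Library scaling does not produce it, since the median was 2.86 after rescaling by the median of ratios. Sensing of the cGAS siRNA pool as foreign RNA may account for it, as the list also stood higher in cGAS_YT than in YT by a median of 2.264, but pool and target are confounded in these groups, so the pool and the loss of cGAS outside STING signalling cannot be told apart.

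Genes lowered by the cGAS or STING siRNAs may in part be direct off-targets of the pools. In cGAS against control the heptamer GCATTCA, present in the cGAS transcript as are 18.8% of heptamers tested, had the strongest association with lower values (z = -14.12; 5th percentile of the strongest value in permuted data -4.36), and 21.9% of 1709 lowered genes and 35.5% of the 234 lowered at least 2-fold carried it against 9.84% of genes not called. In STING against control the heptamer was GTCATAT, present in the STING transcript as are 10.4% of heptamers (z = -9.79, permuted -4.65), carried by 18.5% of 1070 lowered genes and 23.7% of the 114 lowered at least 2-fold against 8.92% of genes not called. Each was near 0 with the other pool (z = -0.13 and 1.09) and returned when the pool was added to the YAP and TAZ siRNAs (z = -10.95 and -7.93). Any of the 5 heptamers past the permuted bound was carried by 45.1% of genes lowered with the cGAS pool (36.6% of genes not called). With the STING pool it was 46.6% (34.2%). These heptamers were chosen for their association with the same changes, so the shares restate it and are no separate evidence. Unlike z, the shares were not adjusted for UTR length and GC content. No biological explanation of the lowered genes was tested.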

How the results depend on the processing

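No paired analysis was possible because no replicate number is shared between groups. Over the named genes and their alternatives, 15875 values stayed on their side of the threshold. Called values that stayed there also kept direction, but direction was not compared where neither value was called, for genes or lists. Another 509 kept direction but lost the call, 33 gained it and 1 reversed. For lists, run with an estimated correlation, fry, rescaling, a pseudocount of 0.25 and each library left out, these numbers were 2703, 116, 59 and 2. The reversals were IL6 in YT against control (-1.42 without YT replicate 3, 1.25 without YT replicate 4), interferon-stimulated genes in cGAS_YT against cGAS (lower without cGAS_YT replicate 9, adjusted p = 2.92e-08; higher without replicate 10, adjusted p = 4.6e-06; up to 0.908 otherwise) and mitochondrial transcripts in the STING interaction (lower without control replicate 1, adjusted p = 0.0365; higher without replicate 2, 7.95e-05; up to 0.917 otherwise). The causes were not tested.

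Counts of changed genes stayed within 1.5 times under other pseudocounts, filters, scaling, edgeR and DESeq2. Exceptions were 3784 in YT against control with only the groups compared and 703 in the STING interaction with a constant prior. Leaving out each library gave 4237 to 6034 for YT against control, 2050 to 4640 for cGAS, 879 to 3101 for STING, 2258 to 4848 for cGAS_YT against cGAS, 3674 to 6339 for STING_YT against STING, 4167 to 6107 for cGAS_YT against YT, 3015 to 5315 for STING_YT against YT, and 1111 to 3270 and 550 to 2555 for the cGAS and STING interactions. The lows came from a lone library in a compared group and the highs from leaving out a YT library.

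Lists past the threshold with an estimated correlation numbered 2, 2 and 0 for YT, cGAS and STING against control, 2 each for cGAS_YT against cGAS and against YT and STING_YT against STING and against YT, and 1 for each interaction. Fry gave 14 for YT against control, 16 for cGAS_YT against YT and 11 for STING_YT against YT. Leaving out each library gave 9 to 11, 6 to 9 and 7 to 8 lists against control, 5 to 7 and 9 to 11 for the doubly treated groups against cGAS and STING, 9 to 10 and 6 to 7 against YT, and 8 to 13 and 5 to 7 for the interactions.

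The median YAP/TAZ effect in STING-depleted cells was -0.49 among the genes lower in YT. Among the genes lower in cGAS_YT against cGAS it was -0.65, against -0.50 for the same genes in YT. Correlations of the YAP/TAZ effect rose to 0.611, 0.773 and 0.807 over genes with a mean of at least 10 CPM. At these depths the simulated interaction test recovered 23.9% of 1.5-fold changes among genes with a mean of at least 5 CPM, so small interactions may often be missed. Recovery among weaker genes, or with as many changed genes as in the real data, was not simulated.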

Other observations

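Single members of the stress response list moved in different directions. HSPA5, the main chaperone of the endoplasmic reticulum, was lower in STING_YT than in STING (-1.06 ± 0.09) and in cGAS_YT than in cGAS (-0.78 ± 0.09), with interactions of -0.96 ± 0.12 and -0.68 ± 0.12. TRIB3 and DDIT3, targets of the integrated stress response, were higher in STING_YT than in STING (1.42 ± 0.10 and 1.26 ± 0.10), and TRIB3 had an interaction with STING siRNAs of 1.49 ± 0.14. CHAC1 was lower after cGAS siRNAs (-1.39 ± 0.11) and lower still in cGAS_YT than in cGAS (-0.76 ± 0.11). In STING_YT against STING 11 of 21 stress response genes rose and 5 fell (11 and 6 adjusted over the list alone), with adjusted p = 0.341 with an estimated correlation, and in cGAS_YT against cGAS 2 rose and 5 fell (2 and 5 adjusted over the list alone; 0.735).

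The glycolytic genes LDHA and ENO1 fell with YAP and TAZ siRNAs in each background, whereas their list did not hold in any with an estimated correlation. By fry the list passed in YT, cGAS-depleted and STING-depleted cells (adjusted p = 0.0015, 0.00864 and 0.000271). LDHA, which makes lactate, fell by 1.49 ± 0.12 in YT, 1.48 ± 0.12 in cGAS_YT against cGAS and 1.87 ± 0.12 in STING_YT against STING, and ENO1, an enolase, fell by 0.90 ± 0.10, 0.90 ± 0.10 and 1.11 ± 0.10. The hypoxia and glycolysis list had 8 lower and 3 higher of 19 in YT, 6 and 3 in the cGAS background and 9 and 2 in the STING background (8 and 3, 6 and 3, and 10 and 2, adjusted over the list alone), with adjusted p = 0.317, 0.399 and 0.25 with an estimated correlation. Mitochondrially encoded transcripts took 5.40% and 5.29% of reads in the STING_YT libraries against 4.14% and 3.52% in the YT libraries, and 8 of 13 were higher in STING_YT than in YT (9 adjusted over the list alone; adjusted p = 0.727 with an estimated correlation).

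Other heptamers were also associated with lower values. In STING_YT against YT the AU-rich TATTTAT, found in the 3' UTRs of 3660 genes, had z = -7.15, behind GTCATAT and CTGGATA (z = -7.50). In YT against control the strongest was GGAACTT (z = -7.86, permuted 5th percentile -4.47). Direct off-targets of the YAP and TAZ siRNAs were not told apart from the loss of YAP and TAZ.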
